A study of Mus musculus with 8 samples.

How the data were processed

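Gene expression in the sciatic nerve of male mice aged 60 days was measured on 8 Agilent 2-colour arrays, 4 from wild-type mice and 4 from SOD1G93A mice, which carry a mutant human SOD1 transgene and are used as a model of amyotrophic lateral sclerosis. Per the labels, nerve RNA carried Cy3 on every array, and a common reference pool of neonatal heart, liver and kidney RNA carried Cy5. No dye was swapped. The labels describe the 4 arrays of a group as biological replicates. All 8 arrays lay on 1 slide with 1 scan date. The first position number on the slide was the same for all arrays of a genotype, so slide position and genotype cannot be told apart.

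The deposited scanner files hold spot intensity on a linear scale for both dyes, with local background intensity and flags, per the file headers written by Agilent Feature Extraction 11.5.1.1. The submitters' processing notes name version 11.0.1.1 of the same program, and limma without a stated role. The deposited series table holds log10 ratios of Cy5 over Cy3. These were the same as the scanner files' own log ratio on every spot, with a largest difference of 0, and 30.7% of them were exactly 0. The median of each array's column was 0. The sign was turned for use here, so that a positive value means more signal in nerve than in the reference. The other deposited values, such as flags and probe names, carry no scale.

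Values were computed from the mean intensity of each spot with the median local background, by normexp correction with an offset of 50 and loess within each array, control spots having no weight. No scaling between arrays was applied. Spots marked as non-uniform or as population outliers were left out, and spots of one probe were averaged. Of 55681 probes, 19836 were well above background in Cy3 on at least 4 of the 8 arrays and were kept. Each gene name was represented by its kept probe with the highest mean Cy3 signal, which gave 15341 rows. Gene names are those of the array's design. The probe accession of 11725 rows matched a transcript of the reference gene table for assembly GRCm38, used for current symbols and for no coordinates. Probe positions are those of the files, on mouse build mm9.

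Genotypes were compared on the log2 ratio of Cy3 to Cy5 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with tables handled by data.table, version 1.17.8. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Unless another setting is named, adjusted p-values of single genes come from this limma fit. Shifts of 29 gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over lists. Lists with under 5 measured genes were not tested. camera with an estimated correlation and fry were run beside it. The lists, the design, the named genes and most alternatives were fixed before the data were examined. The study's title names cytoskeleton genes, so the choice of the cytoskeleton lists is not independent of the study.

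The genes named are Sod1, up to 10 called genes per direction with the largest change and no overlap between groups (filled to 10 with non-overlapping genes of smallest p where fewer were called, which was not needed), 4 members in the direction of each called list, 3 members of each cytoskeleton and Schwann cell list, and 1 member of each other list, members being taken by smallest p. A gene that this rule names is not reported here. The lists of clock genes and of kallikreins, and any other gene named, were chosen after their values were seen.

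The procedure was tested on simulated data with the spread of the 15325 genes complete on all arrays and 200 changed genes per run, over 10 runs. For the comparison of SOD1G93A with wild type, 41.2% of genes changed by 0.5 on the log2 scale were recovered, 84.2% of those changed by 1 and 97.9% of those changed by 2, with 6.9 false calls per run. Simulated genes were independent, so this does not describe sets of correlated genes. The runs held 200 changed genes, while 25 genes were called in the data. The Benjamini-Hochberg threshold is laxer where more genes change, so recovery in the data may be lower. The number of arrays limits the precision.

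Alternatives covered the background correction, normalization within and between arrays, the Cy3 channel alone, the filter on dim probes, a replicate block, array weights, the variance model, the rule for several probes of a gene, the series table's values and leaving out each array in turn. Use of the 6 arrays numbered 2 to 4 was added after seeing the data. Agilent processed signals and the series table gave nearly the same values, such as 3.477 and 3.483 for Gdnf. These 2 alternatives are therefore not independent.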

Results

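The sciatic nerve contains axons of motor and sensory neurons, the Schwann cells that wrap them, and connective, vascular and immune cells. The arrays compared nerves of 4 SOD1G93A mice with nerves of 4 wild-type mice at 60 days of age, and the series title places this age before symptoms. Between 35.5% and 41.7% of the 59305 non-control spots per array were well above background in Cy3, and 0 spots were saturated. Pearson correlations between arrays ranged from 0.88 to 0.98 over genes, which are not independent replicates. The first principal component held 36.4% of the variance and placed wild-type replicate 1 at -33.7 and SOD1G93A replicate 1 at 30.3, with the other arrays between -14.7 and 10.8. Wild-type replicate 1 also had the highest median Cy3 intensity on kept spots, 735.5, and SOD1G93A replicate 1 the lowest, 377.9. The other arrays lay between 536 and 613.2, so this component cannot be read as genotype alone.

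The Sod1 probe, at chromosome 16, 90226509 to 90226568 on mm9, gave a log2 ratio of 0.13 ± 0.20 (SD, n = 4) in wild-type and -0.04 ± 0.09 (SD, n = 4) in SOD1G93A nerves. The difference of -0.17 ± 0.11 (SE) was not called (limma, adjusted p = 0.59). Whether this mouse probe also binds the human transgene was not analysed here, so it does not check the genotype labels.

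The comparison asked which transcripts differ in SOD1G93A nerve. Dbp, a clock-controlled transcription factor, fell by 2.42 ± 0.10 on the log2 scale (SE, limma adjusted p = 1.49e-05), from 3.19 ± 0.17 to 0.77 ± 0.07 (SD, n = 4 per group). Nr1d1 and Nr1d2, nuclear receptors that repress Arntl, fell by 1.59 ± 0.11 and 1.11 ± 0.09 (SE). Arntl, a core activator of the clock, rose by 1.63 ± 0.23 (SE, adjusted p = 0.0426). Jun, a transcription factor induced in Schwann cells after injury, rose by 1.11 ± 0.15 (SE, adjusted p = 0.0390).

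In all, 25 of 15341 genes were called, 11 higher and 14 lower, and at an unadjusted p under 0.01 the count was 547 against 153.4 by chance. In all 25 the groups did not overlap, as was the case for 8.0% of all genes against 2.86% by chance. Genes that pass the threshold rarely overlap, so this is no further support for the 25 calls. The count was not stable, falling to 3 without wild-type replicate 2, wild-type replicate 3 or SOD1G93A replicate 4, to 4 without SOD1G93A replicate 3, and to 9 without wild-type replicate 1 or SOD1G93A replicate 2. It was 16 without wild-type replicate 4 and 180 without SOD1G93A replicate 1, and each of the 25 kept its sign in all of these. Arntl kept its call in 11 of 22 alternatives and Jun in 12 of 22.

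Among the other called genes that were higher, the neurotrophic factor Gdnf was not well above background on any wild-type array and was on all 4 SOD1G93A arrays. Its level was at least 1.45-fold higher by the Cy3 channel, given as a bound because the wild-type signal was not well above background (limma adjusted p = 0.0279). Socs3, an inhibitor of cytokine signalling, rose by 0.81 ± 0.10 (SE) and the adhesion receptor Cd44 by 0.69 ± 0.10 (SE). Hmga1 rose by 0.88 ± 0.11, Midn by 0.77 ± 0.10, and the unnamed probe A_55_P2074381 by 0.76 ± 0.11. Klk1b24, well above background on 2 of 4 wild-type arrays, rose by 1.33 ± 0.19, and its close paralogs make this value uncertain. Tardbp, which encodes TDP-43, rose by 0.62 ± 0.09 on its brighter probe (adjusted p = 0.0495), while its other kept probe gave -0.15 ± 0.09, so the gene's direction is not settled.

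Among the other called genes that were lower, Gm129, now Ciart, was not well above background on any SOD1G93A array and was at least 1.5-fold lower there. Tef, a relative of Dbp, fell by 0.77 ± 0.09 (SE). The cold-inducible RNA-binding protein gene Cirbp fell by 1.12 ± 0.13, Gkn3 by 1.28 ± 0.18, Gstt2 by 1.11 ± 0.16, Trib3 by 0.73 ± 0.10 and Tspan4 by 0.69 ± 0.10. The brighter Nr1d2 probe lies on chromosome 19 in the files and the other on chromosome 14, and the latter gave -0.98 ± 0.09.

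**Figure D1:**
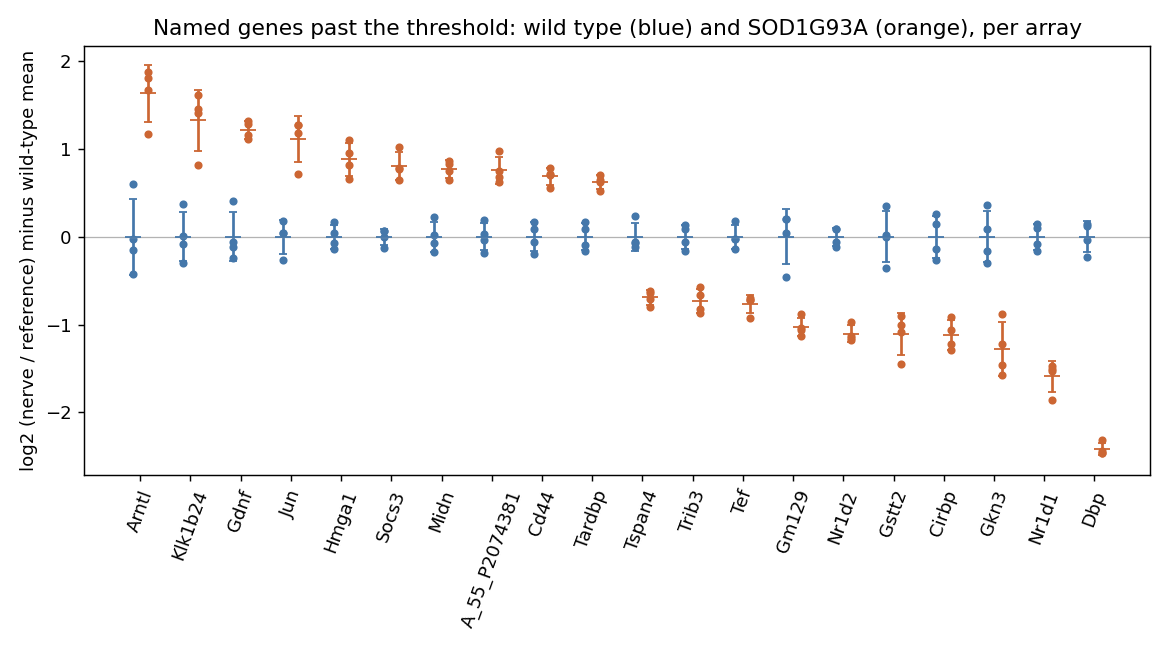
Log2 ratio of nerve to reference minus the wild-type mean (y axis) for the 20 named genes past the threshold (x axis), with a point per array, a bar at the mean and whiskers of 1 SD (n = 4 per group). The groups do not overlap for any of them, which was a condition for naming them, and Dbp has the largest difference, -2.42.

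Cytoskeleton genes, the subject of the series title, gave 1 called list of 4. Of 48 measured microtubule genes, 33 were higher and 0 were called over all genes, against 3 adjusted over the list alone. The list shifted upward by a mean of 0.06 (camera adjusted p = 0.0246), which was lost with an estimated correlation (adjusted p = 0.542). It was also lost without wild-type replicate 1, SOD1G93A replicate 2 or SOD1G93A replicate 4 (camera adjusted p = 0.104, 0.0739 and 0.111), and in the Cy3 channel alone (0.106). The mean was 0.04 without wild-type replicate 1. Spast, which encodes the microtubule-severing protein spastin, gave 0.39 ± 0.07 (SE), the tubulin tyrosine ligase gene Ttl 0.50 ± 0.11, Tuba8 0.33 ± 0.08 and Tubb2b 0.39 ± 0.13. The actin list was not called (62 measured, camera adjusted p = 0.732). Its mean of -0.004 and median of 0.01 differ in sign, and 1 member passed adjusted over the list alone, the Arp2/3 subunit gene Arpc1b at 0.70 ± 0.14, while Flna gave -0.57 ± 0.18 and Iqgap2 -0.29 ± 0.10. Axonal transport genes (49 measured, adjusted p = 0.0847) and intermediate filament genes (16 measured, adjusted p = 0.410) were not called, with 0 members passing adjusted over the list alone, though axonal transport was called upward without wild-type replicate 4 (adjusted p = 0.00965), with Agilent processed signals (adjusted p = 0.0328) and with the series table (adjusted p = 0.0259). The kinesin genes Kif5c and Kif5a gave -0.54 ± 0.16 and -0.35 ± 0.13, Dynll2 0.32 ± 0.11, Gfap 1.12 ± 0.32, Des -0.51 ± 0.23 and Krt18 -0.25 ± 0.12, none of them called. With Agilent processed signals Kif5c gave -0.198 (adjusted p = 0.812), Kif5a -0.169 (adjusted p = 0.804), Iqgap2 -0.579, Gfap 2.36 and Des -0.921. In the Cy3 channel alone Kif5c gave -0.82, Dynll2 0.179 and Krt18 -0.085. On the 6 arrays numbered 2 to 4 Kif5a was called at -0.53 (adjusted p = 0.0368), and Flna was -0.324. Gfap was well above background on 2 of 4 wild-type arrays and Des on 3 of 4 SOD1G93A arrays.

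Genes of non-myelinating and repair Schwann cells were higher as a list, with 13 of 17 measured members above wild type, 2 called over all genes (Jun and Gdnf) and 7 adjusted over the list alone. Members that passed neither adjustment included Gap43 (0.02), Ncam1 (0.10), Scn7a (0.10), Cadm1 (0.11) and L1cam (-0.02), so not all members shared the shift. The list's mean shift was 0.36 and its median 0.14 (camera adjusted p = 3.29e-06, and adjusted p = 0.231 with an estimated correlation). This was the 1 list that fry's test for a shift in 1 direction called, with an adjusted p of 0.0361, while its test for change in either direction called 10 lists. The low-affinity neurotrophin receptor gene Ngfr gave 0.70 ± 0.11 (SE, adjusted p = 0.0547) and the injury-induced Atf3 0.84 ± 0.13 (SE, adjusted p = 0.0590), both short of the threshold. The myelinating Schwann cell list had a mean shift of 0.10 over 31 genes, with 0 passing adjusted over the list alone (camera adjusted p = 0.0144, and 0.791 as the adjusted p with an estimated correlation). The call was lost without wild-type replicate 1 or SOD1G93A replicate 1 (camera adjusted p = 0.664 and 0.821), with scale normalization (0.118) and in the Cy3 channel alone (0.376). The mean was 0.0036 without the former array and 0.0061 without the latter. On the 6 arrays numbered 2 to 4 it was called the other way, with a mean of -0.09 and an adjusted p of 0.0256, so no direction is given. Mpp6 gave 0.50 ± 0.15, Erbb3 0.30 ± 0.10, Dhh 0.27 ± 0.12, Gjb1 0.25 ± 0.14 and Egr2 -0.46 ± 0.15. Erbb3 was well above background on 2 of 4 arrays of each group. For Dhh, the Cy3 channel alone gave -0.00023. Gjb1 was 0.024 on the 6 arrays numbered 2 to 4, 0.092 with array weights and 0.40 in the Cy3 channel alone.

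Immediate early genes, which respond within minutes to stimuli, had 19 of 21 measured members higher, 1 called over all genes and 12 adjusted over the list alone, with a mean of 0.74 (camera adjusted p = 4.89e-12, and adjusted p = 0.313 with an estimated correlation). Fos gave 2.68 ± 0.55 (SE) and Fosl2 0.71 ± 0.16. Heat shock genes had 10 of 27 members passing adjusted over the list alone and a mean of 0.22 (camera adjusted p = 3.29e-06, and adjusted p = 0.542 with an estimated correlation). The score of SOD1G93A replicate 1 was -0.015, inside the wild-type range, against 0.27 to 0.32 on the other SOD1G93A arrays, and the mean was 0.30 without it. Hsph1 gave 1.01 ± 0.15, Hsp90aa1 0.58 ± 0.10, Dnajb1 1.1 ± 0.20 and Hspa8 0.53 ± 0.10. Cell division genes had 14 of 19 members higher, 10 passing adjusted over the list alone, and a mean of 0.27 (camera adjusted p = 1.96e-07, and adjusted p = 0.542 with an estimated correlation). The 5 lower members were Mcm3 (-0.26), Pcna (-0.16), Mcm6 (-0.07), Mcm2 and Mcm5 (-0.02 each). The proliferation marker Mki67 gave 0.83 ± 0.16, Ccnb1, well above background on 2 of 4 wild-type arrays, 0.62 ± 0.14, Prc1 0.47 ± 0.12 and Ccnb2 0.41 ± 0.11. In these lists only Jun was called over all genes.

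Macrophage markers had 19 of 29 members higher and 10 lower, 4 passing adjusted over the list alone, and a mean of 0.28 (camera adjusted p = 0.000784, and adjusted p = 0.721 with an estimated correlation). Lower members included Ptprc (-0.35), Cd74 (-0.30), H2-Aa (-0.24) and H2-Ab1 (-0.23), none of them called. Trem2, a receptor of microglia and macrophages, gave 1.26 ± 0.19 (SE, adjusted p = 0.0508), Ms4a7 1.07 ± 0.22, Cx3cr1 0.93 ± 0.23 and Aif1 0.47 ± 0.12, none past the threshold. The macrophage score on SOD1G93A replicate 1 was -0.30, below all 4 wild-type scores. The mean was 0.48 without that array, 0.16 without SOD1G93A replicate 4 and 0.57 on the 6 arrays numbered 2 to 4. Ribosomal protein genes were higher by a mean of 0.04 over 76 genes, with 0 passing adjusted over the list alone (camera adjusted p = 0.00312, and adjusted p = 0.676 with an estimated correlation), with Rps15a at 0.17 ± 0.08, Rpl3 at 0.14 ± 0.07 and Rpl13a at 0.17 ± 0.09. The ribosomal call was lost without wild-type replicate 3 (camera adjusted p = 0.138), with Agilent processed signals (0.275) and with the series table (0.224). The mean was 0.02 without that array. The brighter Rpl3 probe lies on chromosome 5 in the files and the other on chromosome 15, and the latter gave -0.02, so the value may not be that of Rpl3. The brighter probe was -0.081 in the Cy3 channel alone. Rpl13a was 0.084 on the 6 arrays numbered 2 to 4, 0.094 with Agilent processed signals and 0.089 in the Cy3 channel alone.

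Markers of several other tissues were lower as lists. Scores of the groups overlapped for all of these lists, and for 10 of the 13 called lists in all, the exceptions being repair Schwann cell, immediate early and cell division genes. Endothelial markers had 19 of 21 members lower, 5 adjusted over the list alone, and a mean of -0.44 (camera adjusted p = 1.12e-08, and adjusted p = 0.542 with an estimated correlation). Robo4 gave -0.75 ± 0.13, Esam -0.61 ± 0.14, Emcn -0.55 ± 0.13 and Vwf -0.62 ± 0.16. Pericyte and smooth muscle markers had a mean of -0.62 over 14 genes, with 0 passing adjusted over the list alone (camera adjusted p = 6.11e-05, and adjusted p = 0.542 with an estimated correlation), with Tagln at -0.79 ± 0.22, Acta2 at -1.12 ± 0.39, Myl9 at -0.39 ± 0.14 and Cnn1 at -1.90 ± 0.70. Adipocyte markers had a mean of -0.81 over 20 genes, with 0 passing adjusted over the list alone (camera adjusted p = 3.29e-06, and adjusted p = 0.641 with an estimated correlation), with Plin4 at -1.65 ± 0.53, Pck1 at -1.76 ± 0.62, Mgst1 at -1.27 ± 0.48 and Fabp4 at -1.36 ± 0.55. Without SOD1G93A replicate 4, whose score was -1.64 against -0.74 to -0.33 on the other SOD1G93A arrays, the adipocyte mean was -0.54. Wild-type replicate 4 scored -0.79 for adipocyte, -0.54 for pericyte and -0.28 for endothelial markers, against SOD1G93A values up to -0.33, -0.46 and -0.24. Wild-type replicates 1 and 2 scored 0.72 and 0.37 for adipocyte and 0.56 and 0.29 for pericyte markers. Wild-type replicate 3 scored -0.30 and -0.31 for these lists. Without wild-type replicate 1 the adipocyte mean was -0.57 and the pericyte mean -0.43. Skeletal muscle markers had a mean of -1.35 over 16 genes, with 0 passing adjusted over the list alone (camera adjusted p = 3.29e-06, and adjusted p = 0.542 with an estimated correlation), with Tnnt3 at -1.62 ± 0.59, Actn3 at -1.53 ± 0.58, Myh4 at -2.29 ± 0.90 and Tnnc2 at -2.60 ± 1.1. Actn3 was well above background on 2 of 4 SOD1G93A arrays, and Myh4 on 3 of 4 wild-type and 1 of 4 SOD1G93A arrays. Without wild-type replicate 1 the muscle mean was -0.81. On the 6 arrays numbered 2 to 4 Actn3 was -0.98 and Mgst1 -0.69, while Myh4 was -3.62 in the Cy3 channel alone. The muscle scores of wild-type replicates 1 and 2 were 1.60 and 0.79, while replicates 3 and 4, at -1.28 and -1.11, lay close to the SOD1G93A arrays, at -1.44 to -1.16. Interferon response genes had a mean of -0.21 over 21 genes, with 0 passing adjusted over the list alone (camera adjusted p = 0.00225, and adjusted p = 0.718 with an estimated correlation), with Ifit2 at -0.23 ± 0.08, Gbp3 at -0.48 ± 0.17, Usp18, well above background on 3 of 4 SOD1G93A arrays, at -0.35 ± 0.14 and Gbp2 at -0.40 ± 0.18. That call was lost without wild-type replicate 1 or SOD1G93A replicate 4 (camera adjusted p = 0.0997 and 0.0585), and the mean was -0.11 and -0.14 without them. Gbp2 was -0.155 on the 6 arrays numbered 2 to 4 and -0.233 with array weights.

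**Figure D2:**
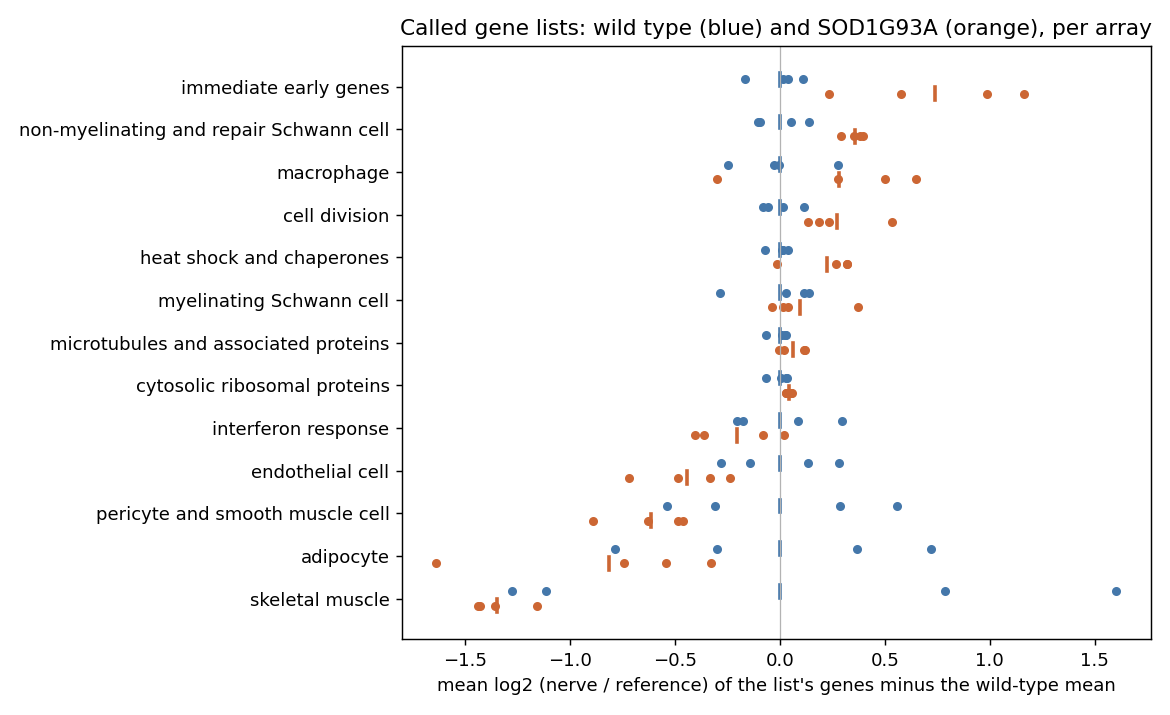
Mean log2 ratio of each called list's genes minus the wild-type mean (x axis) for the 13 lists called by camera at the preset correlation (y axis), with a point per array and a bar at each group's mean (n = 4 per group). Repair Schwann cell scores of the groups do not overlap, while skeletal muscle scores of the wild-type arrays spread from -1.28 to 1.60.

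The remaining lists were not called by camera on all 8 arrays. Among them, fry's test for change in either direction called endoplasmic reticulum stress (adjusted p = 0.000442), inflammatory mediators (adjusted p = 0.000707), genes mutated in amyotrophic lateral sclerosis (adjusted p = 0.00288) and axon guidance (adjusted p = 0.0437), a test that compares no list with other genes. The camera adjusted p was 0.105 for mast cells (Hdc -0.27 ± 0.13), 0.388 for fibroblasts and matrix (Timp1 0.65 ± 0.13), 0.993 for the perineurium (Tjp1 -0.16 ± 0.13), 0.761 for red blood cells (Fech -0.16 ± 0.09) and 0.388 for antioxidant defence (Gclc -0.39 ± 0.12). It was 0.262 for endoplasmic reticulum stress (Trib3 called lower), 0.463 for oxidative phosphorylation (Atp5o 0.19 ± 0.08), 0.987 for lipid synthesis (Hsd17b7 -0.40 ± 0.17) and 0.987 for inflammatory mediators (Socs3 called higher). It was 0.723 for trophic factors (Gfra3, a receptor subunit for artemin, -1.62 ± 0.31), 0.987 for axon guidance (Robo4) and 0.228 for genes mutated in amyotrophic lateral sclerosis (Tardbp). Only 3 T and natural killer cell genes were measured, and that list was not tested (Cd3e -0.20 ± 0.09). On the 6 arrays numbered 2 to 4 Tjp1 was -0.016, Hdc -0.17, Fech -0.085 and Gclc -0.22. With array weights Tjp1 was -0.040. Mast cell markers were called lower without wild-type replicate 2, wild-type replicate 4 or SOD1G93A replicate 2 (camera adjusted p = 0.0123, 0.0175 and 0.0386) and with no filter on dim probes (0.0281). Endoplasmic reticulum stress genes were called higher without SOD1G93A replicate 1 (adjusted p = 0.0484), with array weights (0.0441) and on the 6 arrays numbered 2 to 4 (0.01001). Lipid synthesis genes were called lower without wild-type replicate 1 (adjusted p = 0.000247), with array weights (0.0416) and on the 6 arrays (7.95e-06). On the 6 arrays red blood cell markers were also called lower (0.0247) and oxidative phosphorylation genes higher (0.0311).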

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

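All tests in this part were chosen after the results they bear on had been seen, and the margins required of a bound were set after the first values of these tests. Of 252 groups of 4 arrays examined for an array far from the other 3, 17 had one (6.75%), and chance gives about 5%. SOD1G93A replicate 1 was such an array for Nr1d1 (0.16), Erbb3 (0.84), Gjb1 (3.62), Cd3e (0.28), Hsph1 (1.69) and for the scores of heat shock (-0.015), oxidative phosphorylation (-0.30) and inflammatory mediator genes (-0.29). Wild-type replicate 1 stood apart for Gjb1 (2.70) and lipid synthesis (-0.43), wild-type replicate 2 for Tspan4 (0.40) and Trem2 (1.15), SOD1G93A replicate 3 for Actn3 (0.093) and Usp18 (0.11), and SOD1G93A replicate 4 for Tef (0.73), Plin4 (0.25) and Myh4 (0.77). The Cy5 channel held the same reference pool on every array. It gave 39 called genes of 19998 between genotypes, of up to 0.56 on the log2 scale. Of them 1, Dbp at -0.29, was also called in nerve. Since the pool was shared, these calls point to a technical difference between the groups' arrays, whose cause was not tested. Among other genes called in nerve, Socs3 (0.30), Nr1d1 (-0.25) and Tef (-0.18), for example, moved in Cy5 as in nerve, without a call there. Arntl (-0.01) and Gdnf (-0.06), for example, moved against their nerve change.

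Of the 35 splits of the 8 arrays into groups of 4, only the genotype split called as many as 25 genes (1 of 35). The highest other split called 2. This argues against chance for the gene count in the main setting, the only setting in which splits were compared. Splits cannot address causes that go with genotype, such as slide position. For the list count chance stays open: 10 of the 35 splits called at least 13 lists, and the highest other split called 17.

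Clock genes differed between the genotypes. A difference in the Cy5 reference was argued against: Cy3 alone showed a median of 98.6% of the log ratio change over the 15 measured clock genes. A slide position effect on both dyes was also argued against, since at the same probes the median Cy5 change was 1.55% of the Cy3 change, with a spread of 11.54 points, while an effect of position on Cy3 alone stays open. All 11 phased genes (100%), 8 that peak with Dbp and 3 that peak with Arntl, moved by their phase, but they were chosen after Dbp and Arntl were seen to change, so this restates the pattern. Nerves taken at a different time of day and a clock shifted by genotype both stay open, and cannot be told apart because no label used here gives the time of dissection.

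Repair Schwann cell genes were higher as a list at the preset correlation but not called with an estimated one (adjusted p = 0.231), with 4 of 17 members lower and 2 called over all genes. Without Jun and Atf3, which are also immediate early genes, 76.9% of the mean shift was left, with a spread of 21.5 percentage points, so a response to handling may contribute and is not excluded. The arrays numbered 1 were argued against as the whole cause, since without both 89.0% was left, with a spread of 21.6 points. The scores were -0.10 to 0.14 in wild type and 0.29 to 0.40 in SOD1G93A. The bound for this question was looser than that for handling, by which 89.0% would decide nothing, so a part played by these arrays stays open. An early reaction of Schwann cells to the transgene stays open as a hypothesis.

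Markers of muscle, fat and vessels were lower as lists at the preset correlation, but with an estimated correlation none was called, and 0 muscle, adipocyte or pericyte genes but 5 of 21 endothelial genes passed adjusted over their list alone. Of all pairs of wild-type arrays, leaving out replicates 1 and 2 left least of the skeletal muscle shift, 11.2% with a spread of 7.77 points, and of the endothelial shift, 52.6% with a spread of 28.2 points. Of the 3 brightest muscle genes, Eno3 and Tcap were higher in Cy3 on those 2 arrays than on every other, and Mb was not. Muscle tissue on these 2 nerves may therefore account for the muscle shift but is not settled, and the endothelial value decides nothing. Adipocyte and pericyte scores were also highest on wild-type replicates 1 and 2, but pairs were not left out for these lists. A loss of vessels in SOD1G93A nerve is untested.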

How the results depend on the processing

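All alternatives were fixed before the data were examined except the use of the 6 arrays numbered 2 to 4, chosen after seeing the data. The count of 25 called genes stayed within 1.5 times of itself with no background correction, scale, Cy3 alone, the all-array filter, the other variance model and both other probe rules. Aquantile changed no log ratio, with a largest difference of 0, so it tests nothing here and is not counted below. The count was 7 with Agilent processed signals, 7 with the series table, 1 with median centring, 16 with no filter on dim probes, 421 with array weights, 547 at an unadjusted p under 0.01 and 234 on the 6 arrays numbered 2 to 4. Leaving out each array gave 3 to 180. The cause was not tested, except that more rows were tested without the filter. With the replicate block 1 gene and 13 lists were called. The replicate number was also the second slide position number in both groups. Same-numbered arrays had correlations of -0.16, 0.04, -0.11 and 0.10 between their deviations, and no wild-type array correlated best with its own number. By these values over all genes the numbers do not pair the arrays. In Cy3 alone 62.9% of the called genes were higher, against 44.0%. Dbp was called in all 22 alternatives run for it, and Nr1d1 and Nr1d2 in 20 of 22. Agilent processed signals and the series table are both among these 22, though they nearly repeat each other. The other 17 named called genes kept their call in 7 to 13 of 21 or 22 alternatives, among them Arntl in 11 and Jun in 12. Sod1 was called in none. The count of 13 called lists became 0 with an estimated correlation and 1 with fry's test for 1 direction. Signal over background limits Gdnf and Gm129, and the genes said to be well above background on only some arrays of a group.

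Lists whose direction turned had these adjusted p-values, and the cause was not tested. With no background correction they were 0.991 for cholesterol and fatty acid synthesis. With Agilent processed signals centred on the median they were 0.906 for perineurial and tight junction, 0.906 for inflammatory mediators, 0.906 for axon guidance. With median centring they were 0.918 for perineurial and tight junction, 0.822 for red blood cell, 0.708 for oxidative phosphorylation, 0.822 for axon guidance. With scale after loess they were 0.982 for red blood cell, 0.854 for cholesterol and fatty acid synthesis. With Cy3 channel alone with quantile normalization they were 0.952 for perineurial and tight junction, 0.948 for oxidative phosphorylation, 0.413 for cholesterol and fatty acid synthesis, 0.924 for inflammatory mediators, 0.924 for axon guidance. With no filter on dim probes they were 0.737 for perineurial and tight junction, 0.769 for cholesterol and fatty acid synthesis, 0.769 for axon guidance. With well above background on all 8 arrays they were 0.983 for cholesterol and fatty acid synthesis. With replicate block they were 0.988 for cholesterol and fatty acid synthesis, 0.988 for inflammatory mediators. With array weights they were 0.83 for actin cytoskeleton and its regulators, 0.782 for intermediate filaments, 0.826 for myelinating Schwann cell, 0.453 for perineurial and tight junction, 0.276 for oxidative phosphorylation, 0.0416 for cholesterol and fatty acid synthesis, 0.596 for axon guidance. With every kept probe they were 0.754 for inflammatory mediators. With mean of the gene's probes they were 0.937 for inflammatory mediators. With series matrix values they were 0.923 for perineurial and tight junction, 0.923 for inflammatory mediators, 0.923 for axon guidance. With the 6 arrays numbered 2 to 4 only they were 0.913 for actin cytoskeleton and its regulators, 0.957 for axonal transport motors and adaptors, 0.338 for intermediate filaments, 0.0256 for myelinating Schwann cell, 0.739 for mast cell, 0.317 for perineurial and tight junction, 0.801 for antioxidant defence, 0.0311 for oxidative phosphorylation, 7.95e-06 for cholesterol and fatty acid synthesis, 0.498 for axon guidance. With fry they were 0.97 for cholesterol and fatty acid synthesis, 0.815 for axon guidance. Over the fits without 1 array each, lists that turned in any of them ranged from 0.491 to 0.87 for actin cytoskeleton and its regulators, 0.211 to 0.982 for intermediate filaments, 0.193 to 0.927 for perineurial and tight junction, 0.165 to 0.957 for red blood cell, 0.207 to 0.848 for antioxidant defence, 0.0645 to 0.672 for oxidative phosphorylation, 0.000247 to 0.845 for cholesterol and fatty acid synthesis, 0.332 to 0.963 for inflammatory mediators, 0.472 to 0.995 for trophic factors and receptors, 0.365 to 0.942 for axon guidance. With Agilent processed signals and with the series table the values of Klk1b24, Gdnf, Gm129, Iqgap2, Kif5c, Kif5a, Gfap, Des, Erbb3, Usp18, Ccnb1, Ccnb2, Rpl3 and Rpl13a moved by over 1.5 times. Among named genes, Dhh (-0.00023) and Rpl3 (-0.081) turned in Cy3 alone, neither of them called.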

Other observations

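The lists in this part were chosen after seeing the data, so their values describe and do not test. Of 15 measured clock genes, 7 were called. All 8 measured genes that peak with Dbp were lower and all 3 that peak with Arntl were higher, including Nfil3 at 1.69, Clock at 0.55, Per1 at -1.05, Per3 at -0.78 and Hlf at -0.67, which missed the threshold. Per3 was well above background on 3 of 4 SOD1G93A arrays. The called gene Cry2 was at -0.61.

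All 8 measured tissue kallikrein genes were higher, from 1.33 for Klk1b24 to 2.93 ± 0.47 (SE) for Klk1b5, and only Klk1b24 was called over all genes. These paralogs are near-identical in places, so their probes are not independent, and Klk1b4 and Klk1b8 were, like Klk1b24, well above background on 2 of 4 wild-type arrays. The family's score was 1.00 on wild-type replicate 4 against -0.69 to -0.14 on the other wild-type arrays, and 1.43 to 2.72 on the SOD1G93A arrays.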
